A study of Homo sapiens with 59 samples.

How the data were processed

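Bulk RNA was sequenced from A549 cells, an established human lung carcinoma line, after 24 h with 1 of 8 herbal medicines or with vehicle. Each medicine was a 70% ethanol extract, given at a high, a medium and a low dose. Per the labels, libraries were strand-specific mRNA libraries, read as 100 bp pairs. The deposited table holds 60675 Ensembl genes and, beside the columns used here, 210 per-sample columns that belong to other series and were not used here. The 59 columns of this series were matched to samples by the code in each sample description.

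Per the submitters' processing notes, the reads passed through FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3, with builds hg38 and GRCh38 named; the annotation release is not given in the sources used here. The deposited values are expected counts per gene, not scaled for depth, as the authors' table gives them. Of the values in genes not at 0 throughout, 84.4% were whole numbers, and the others carried decimals. Expected counts were rounded to whole numbers before testing. Totals ran from 17214755 to 39751161 expected counts per library. Symbols were found for 56558 of the gene IDs, and positions are those of GENCODE 29 on GRCh38, which held 94% of the IDs.

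Groups were taken from the labels: 25 groups of 1 to 3 libraries, 1 of them the vehicle with 3 libraries. Each sample description holds a library code, and its first number was read as a library set, which the labels do not explain; the titles give a single batch name to all 59 libraries, vehicle included. Set 11 held Coptidis Rhizoma and Zizyphi Fructus, set 12 Citri Unshius Pericarpium and Cimicifugae Rhizoma, set 13 Bupleuri Radix and Aconiti Lateralis Radix Preparata, and set 14 Yijung-tang and Banhasasim-tang. The 3 vehicle libraries carry a code of their own, so a difference between a set and the vehicle cannot be told apart from an effect shared by both extracts of that set. The high dose against the low dose of an extract, and extract against extract within a set, do not use the vehicle and compare libraries of 1 set. The sample labels give 0.1% DMSO for the vehicle and the series text gives 2%; this disagreement could not be settled from the data. The labels do not say whether replicates came from separate cultures, so every p-value measures only the spread between these libraries.

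Differential expression was tested with edgeR 4.0.16 (quasi-likelihood) in R 4.3.3. Counts were scaled by TMM, genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, and 18568 genes were tested, 16261 of them with a symbol. A single model with 25 group means was fitted to the 59 libraries (34 residual degrees of freedom, prior degrees of freedom 4.64). P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene is called at an adjusted p below 0.05. Were no gene changed, about 0.05 of the tested genes would have an unadjusted p below 0.05. There were 31 comparisons: 21 of a dose against vehicle, 7 of a high against a low dose and 3 between extracts of a set. Banhasasim-tang had 1 library per dose; its values are given as folds over the vehicle mean, with no test. Tested log2 fold changes are those of the edgeR fit with its default prior count. The plus or minus is a standard error taken as the absolute log2 fold change divided by the square root of the F statistic. A prior count of 2 was used for log2 CPM, which entered camera, fry, the principal components, the correlations and the Banhasasim-tang log2 folds. CPM values are TMM-normalized counts scaled to CPM, given as mean and SD.

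In total 27 gene lists with 485 members, 446 of them measured, were fixed together with the groups, the comparisons, the tests, the other settings and the rule for named genes before the data were examined. The lists are AhR targets, NRF2 targets, cholesterol synthesis and uptake, LXR targets, fatty acid synthesis, ATF4 targets, ER chaperones and unfolded protein response, heat shock proteins, metallothioneins and zinc export, p53 targets, G2/M and mitosis, DNA replication, NF-kB and inflammatory genes, interferon-stimulated genes, glycolysis and hypoxia, glucocorticoid receptor targets, TGF-beta and mesenchymal genes, MAPK and immediate early genes, lysosome and autophagy, FOXO targets, nuclear-encoded respiratory chain, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis, PXR and CAR targets, lung epithelial markers, and markers of other cell types. Each list was tested against the other genes with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, and on its own with fry; the p-values were adjusted over the 27 lists.

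In the tested comparisons the largest rises and falls had to be called, with every treated library beyond every comparison library, a mean of at least 5 CPM in the higher group, and a proper symbol. Genes named from the lists had only to be called. Genes carried from the high dose to the medium and low doses needed no call there. At each high dose the text names from the 6 largest rises and 6 largest falls, and from the 3 members with the smallest p of the 6 lists with the largest called share. At medium and low doses it names those genes and the 2 largest rises and falls, and in the other comparisons the 4 largest rises and falls. For Banhasasim-tang it names the 5 largest rises and falls. CYP1A1, CYP1B1, HMGCS1, ASNS, TRIB3, HMOX1 and CDKN1A may be named in every comparison, whatever they did. Some genes that the rule names are not reported here. Genes outside this rule are marked as chosen after their values were seen.

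The other settings tried were size factors of the DESeq2 type (RLE) in edgeR, the DESeq2 1.42.0 Wald test, no low-count filter, fits of the extracts compared with or without the vehicle, the replicate number as a block, each replicate left out in turn, camera with an estimated correlation, a prior count of 0.5 for the Banhasasim-tang folds, and genes with a mean log2 CPM of at least 3 for the correlations. A fit without 4 libraries that had over 1000 CPM in antisense noncoding genes was added after the data had been seen. Similarity between extracts was the Pearson correlation across genes of high minus low log2 fold changes. Classes of noncoding genes were made from the annotation with bedtools 2.31.1, and their shares, in CPM, are of the library total with no TMM scaling, and figures with Python 3.11.15 and matplotlib 3.10.9. The test was also tested on simulated data with 100 genes changed 2-fold and 100 changed 1.5-fold. These were drawn from genes with a mean of at least 1 CPM, so the recovery does not cover weaker genes. At 2-fold it recovered 82% of them in a comparison of 2 and 3 libraries and 91% in 1 of 3 and 3. At 1.5-fold it recovered 45% and 55%, and there were 6 and 5 false calls. The simulated counts had 1 dispersion per gene, the same in all 59 libraries, and no set difference or deviating library. The false calls therefore do not show how the fit behaves where such differences are present. Wortmannin, which the series text names, was in no library used here.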

Results

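RNA levels were measured in 59 libraries of A549 cells after 24 h with a herbal extract or with vehicle (n = 3). Coptidis Rhizoma was given at 110, 22 and 4.4 µg/mL and Bupleuri Radix at 190, 38 and 7.6 µg/mL. The other 6 medicines, Zizyphi Fructus, Citri Unshius Pericarpium, Cimicifugae Rhizoma, Aconiti Lateralis Radix Preparata, Yijung-tang and Banhasasim-tang, were given at 500, 100 and 20 µg/mL. Yijung-tang and Banhasasim-tang are formulas of several medicines, and the others are single medicines. Each dose had 3 libraries for Citri Unshius Pericarpium, Cimicifugae Rhizoma and Bupleuri Radix, and 2 for Coptidis Rhizoma, Zizyphi Fructus and Yijung-tang. Aconiti Lateralis Radix Preparata had 3, 2 and 3 libraries at the high, medium and low dose, and Banhasasim-tang had 1 at each. Totals ran from 17214755 to 39751161 expected counts per library. The comparisons asked which genes each extract changed at each dose against vehicle, and which genes set the high dose apart from the low dose.

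Counts in antisense noncoding genes and in mitochondrial rRNA differed between libraries. Antisense noncoding genes took 747.1 to 813.7 CPM in the vehicle libraries, at most 873.3 in 55 libraries, and 1190 to 2254 in the remaining 4. These 4 were replicate 3 of Citri Unshius Pericarpium at the high and medium dose and replicate 2 of Cimicifugae Rhizoma at the medium and low dose. On the first principal component, which held 45% of the variance, these 4 had 25.59 to 70.06, against at most 16.8 in the other libraries. The library codes of these 4 are consecutive. The code just before them is replicate 2 of Cimicifugae Rhizoma at the high dose (825.2 CPM). The code just after them is replicate 3 of Citri Unshius Pericarpium at the low dose (873.3 CPM). In another set, replicate 1 of Aconiti Lateralis Radix Preparata at the medium dose had 872.1 CPM. Mitochondrial rRNA (MT-RNR1 and MT-RNR2 together) took 2.24% to 2.43% of the vehicle counts, 6.09% to 11.2% in the 6 Coptidis Rhizoma libraries, and 3.87% to 15.2% in the 3 of Banhasasim-tang. Replicate 2 of Citri Unshius Pericarpium at the medium dose, not among these 4 libraries, had the fewest counts in sense-intronic genes (126.2 CPM, against 221.4 to 227.9 in vehicle) and the highest value on the third principal component (26.9). Because a single fit shares its spread over all groups, the 4 libraries of high antisense share entered every count of called genes. Counts of called genes against vehicle, between doses and between extracts are therefore also given without them, a choice made after the data had been seen. They are also given from a fit of only the extract or extracts compared, with the vehicle where it is compared, a setting fixed beforehand. The medium against the high dose of Aconiti Lateralis Radix Preparata, a comparison added later, was not fitted in this way.

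**Figure D1:**
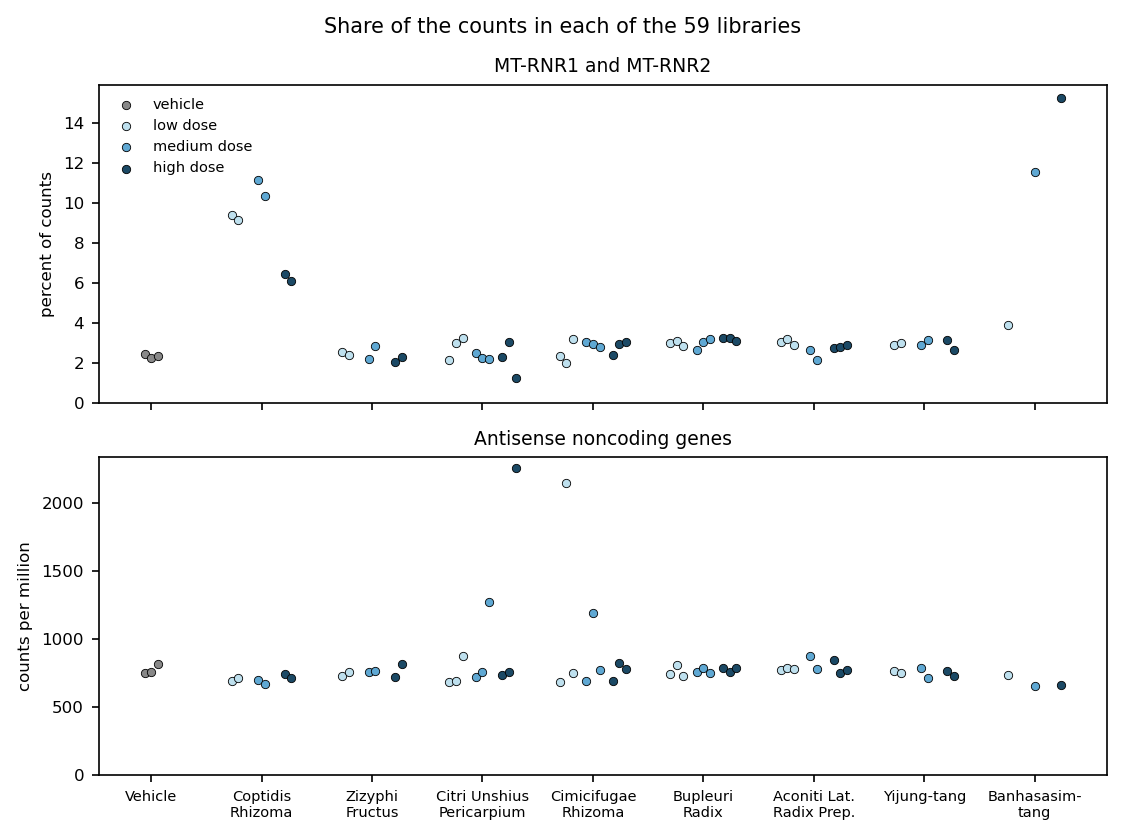
Percent of counts in mitochondrial rRNA (upper panel) and CPM in antisense noncoding genes (lower panel), 1 point per library, by extract and dose. Coptidis Rhizoma and Banhasasim-tang libraries lie at 3.87% or more in the upper panel, and 4 libraries lie at 1190 or more in the lower panel.

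Coptidis Rhizoma at the high dose raised genes of the aryl hydrocarbon receptor (AhR) and of the amino acid stress response, and lowered genes of cholesterol synthesis, the cell cycle and heat shock proteins. CYP1A1, a xenobiotic-metabolizing enzyme and AhR target, was at 11.1 ± 0.705 CPM (SD, n = 2) against 0.749 ± 0.144 CPM in vehicle (n = 3), 14.6-fold higher; CYP1B1 rose 4.31-fold and AHRR, the AhR repressor, 3.72-fold. TRIB3, a pseudokinase induced by the transcription factor ATF4, was at 290 ± 1.2 against 69.5 ± 3.21 CPM. INSIG1, which holds back the sterol-sensing machinery, fell to 0.387 of vehicle. The mitochondrial 12S rRNA MT-RNR1 was at 21000 ± 512 against 1560 ± 98.8 CPM.

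By list, 5 of 6 AhR targets rose at the high dose of Coptidis Rhizoma (camera adjusted p = 6.98e-12). Of 25 ATF4 targets, 19 rose (1.97e-22), among them SESN2, which restrains mTORC1, by 1.97 ± 0.17 on the log2 scale, PCK2 by 1.59 ± 0.13 and ASNS, the asparagine synthetase, by 1.28 ± 0.18. Cholesterol synthesis and uptake had 19 of 24 members lower and none higher (2.11e-25), with HMGCS1, which makes HMG-CoA, at a log2 change of -0.81 ± 0.13. In G2/M and mitosis 23 of 25 members fell (2.11e-25), including the cyclin gene CCNB1 (-0.72 ± 0.09) and the mitotic kinase gene AURKA (-0.78 ± 0.1). DNA replication had 22 of 29 members lower (1.98e-22), with the helicase gene MCM4 at -0.68 ± 0.07. Of 15 heat shock proteins 13 fell (1.57e-13), HSPA1A by a log2 change of -0.94 ± 0.13, and of 22 p53 targets 9 rose (2.51e-06), CDKN1A by 0.57 ± 0.11. These 7 lists kept a camera adjusted p below 0.05 with an estimated correlation, the highest being 0.00405 for ATF4 targets.

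The other 6 lists that passed camera with the preset correlation at this dose did not pass with an estimated correlation. They were NF-kB and inflammatory genes (7 of 18 higher), fatty acid synthesis (6 of 10 lower) and ER chaperones (4 higher and 7 lower of 19), each at an adjusted p = 0.0505 with an estimated correlation; MAPK and immediate early genes (10 of 22 higher, adjusted p = 0.231); mitochondrially encoded genes (4 of 13 lower, adjusted p = 0.302); and the nuclear-encoded respiratory chain (1 of 24 lower, adjusted p = 0.704). Adjusted over the list alone, the counts were 5 AhR targets, 19 higher and 2 lower ATF4 targets, 21 cholesterol genes, 25 G2/M genes, 24 DNA replication genes, 14 heat shock proteins and 10 p53 targets. Outside the lists, NIBAN1, a stress-induced gene, was at 103 ± 2.01 against 11.1 ± 0.802 CPM, and GREM1, a BMP antagonist, rose 8.93-fold. The largest falls included the orphan nuclear receptors NR4A3 (log2 change -2.45 ± 0.29) and NR4A1 (-2.07 ± 0.24), the neuronal pentraxin NPTX1 (-1.98 ± 0.11) and the imprinted noncoding RNA H19 (-1.78 ± 0.25). HMOX1, the heme oxygenase induced by NRF2, had 173 ± 2.84 CPM against 168 ± 8.57 (adjusted p = 0.896). Of the genes named by the rule, EIF3CL, a near copy of EIF3C, had 87.7 ± 59 CPM in its 2 libraries and lost its call in 6 of 11 alternatives.

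In all, edgeR called 2332 genes at the high dose of Coptidis Rhizoma against vehicle, 1191 higher and 1141 lower, 5100 without the 4 libraries of high antisense share and 7089 in a fit of only the Coptidis Rhizoma and vehicle libraries. Without its high-dose replicate 2 or 3 the count was 1164 or 1177. CYP1A1 lies on chromosome 15 (ENSG00000140465, 74719542 to 74725610), CYP1B1 on chromosome 2 (ENSG00000138061, 38066973 to 38109902) and TRIB3 on chromosome 20 (ENSG00000101255, 362835 to 397559), each on GRCh38.

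At the medium and low doses of Coptidis Rhizoma AhR and ATF4 targets were again higher and cholesterol genes lower than in vehicle. CYP1A1 was at 6.99 ± 0.193 CPM at the medium and 2.93 ± 0.624 CPM at the low dose, TRIB3 at 219 ± 1.18 and 155 ± 7.77 CPM, and INSIG1 at 18.5 ± 0.0224 and 21.9 ± 0.284 CPM (n = 2 each), against 0.749 ± 0.144, 69.5 ± 3.21 and 36.3 ± 1.53 CPM in vehicle. These 6 changes were called, and CYP1A1, TRIB3 and INSIG1 lost no call at either dose in the 11 alternatives run for each. At the medium and low dose 5 and 2 of 6 AhR targets rose (estimated-correlation adjusted p = 5.29e-07 and 1.17e-05), 17 and 10 of 25 ATF4 targets rose (0.00107 and 0.00131), and 12 and 5 of 24 cholesterol genes fell (3.73e-08 and 5.86e-08). Heat shock proteins had 8 and 0 of 15 lower (9.79e-05 and 0.000276), G2/M genes 7 and 0 of 25 (0.000163 and 0.00656) and DNA replication genes 8 and 1 of 29 (7.73e-07 and 8.49e-05). Of 22 p53 targets 2 and 0 were higher (0.0456 and 0.801). With adjustment over the list alone, ATF4 targets had 19 and 16 higher and cholesterol genes 15 and 14 lower. MT-RNR1 was at 32600 ± 727 CPM at the medium and 27300 ± 542 CPM at the low dose. At the low dose MT-ND6, a mitochondrial mRNA, also rose 6.54-fold. The medium dose had 607 called genes (327 higher, 280 lower) and the low dose 83 (56 higher, 27 lower); without the 4 libraries of high antisense share these were 2252 and 643. A fit of only the Coptidis Rhizoma and vehicle libraries called 4185 at the medium dose and 2126 at the low dose, where 47.1% were higher, against 67.5% with all libraries. The medium-dose count was 234 without medium-dose replicate 2, 228 without replicate 3, 401 without vehicle replicate 1 and 383 without vehicle replicate 3. The low-dose count was 32 and 28 without low-dose replicate 2 and 3, and 54, 53 and 54 without vehicle replicate 1, 2 and 3.

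Against its low dose, the high dose of Coptidis Rhizoma had higher AhR targets and lower cell cycle and cholesterol genes, and lower MT-ND5 and MT-CYB, 2 mitochondrial mRNAs. BEX2 was 4.45-fold, CYP1A1 3.78-fold, GREM1 3.68-fold and NIBAN1 3.54-fold higher at the high dose. MT-ND5, a subunit of respiratory complex I, was at 1460 ± 157 CPM at the high and 15500 ± 1880 CPM at the low dose, and MT-CYB at 2360 ± 175 and 14400 ± 1260 CPM. TRIB3 was 1.88-fold higher (adjusted p = 0.00507), a call lost without high-dose replicate 2 or either low-dose replicate. AhR targets were higher in 4 of 6, and G2/M genes lower in 13 of 25, DNA replication genes in 8 of 29 and cholesterol genes in 9 of 24 (estimated-correlation adjusted p = 3.06e-06, 2.95e-06, 1.81e-08 and 2.04e-07); adjusted over the list alone these were 4, 23, 22 and 13. Mitochondrially encoded genes had 5 of 13 lower (camera adjusted p = 1.78e-11; adjusted p = 0.0807 with an estimated correlation). There were 429 called genes, 173 higher and 256 lower at the high dose, 1643 without the 4 libraries of high antisense share and 4206 in a fit of only the Coptidis Rhizoma libraries. The count was 110 and 150 without high-dose replicate 2 and 3, and 128 and 132 without low-dose replicate 2 and 3.

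With Zizyphi Fructus the main edgeR fit called no gene at any dose, but some were called in other settings, also with all libraries. At its high dose CYP1A1 had 1.29 ± 0.19 CPM (n = 2) against 0.749 ± 0.144 in vehicle (adjusted p = 1), CYP1B1 66.6 ± 1.03 against 55.3 ± 2.88 (adjusted p = 1) and HMGCS1 195 ± 2.83 against 201 ± 4.22 (adjusted p = 1). TRIB3 had 65.4 ± 0.748 CPM and HMOX1 160 ± 10.1 CPM. The AhR target list had a camera adjusted p = 0.0356 in the upward direction with 0 of 6 members called, and an adjusted p = 0.125 with an estimated correlation. With the replicate number as a block 5 lists passed camera, AhR targets (adjusted p = 0.0361) and PXR and CAR targets upward and ATF4 targets, the respiratory chain and ribosomal proteins downward (adjusted p = 0.0409 each). edgeR called 0 genes at the high, medium and low dose, and DESeq2 called 3, 2 and 0. At an unadjusted p below 0.05 there were 439, 497 and 460 in edgeR, each fewer than 0.05 of the tested genes. Without the 4 libraries of high antisense share the edgeR counts were 7, 2 and 0, with no low-count filter 27, 61 and 40, and in a fit of only the Zizyphi Fructus and vehicle libraries 2, 19 and 0. Its high dose against its low dose gave 0 genes in edgeR, 0 in DESeq2, 0 without the 4 libraries and 0 in a fit of only its own libraries. At an unadjusted p below 0.05 this comparison had 251, again fewer than 0.05 of the tested genes.

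**Figure D2:**
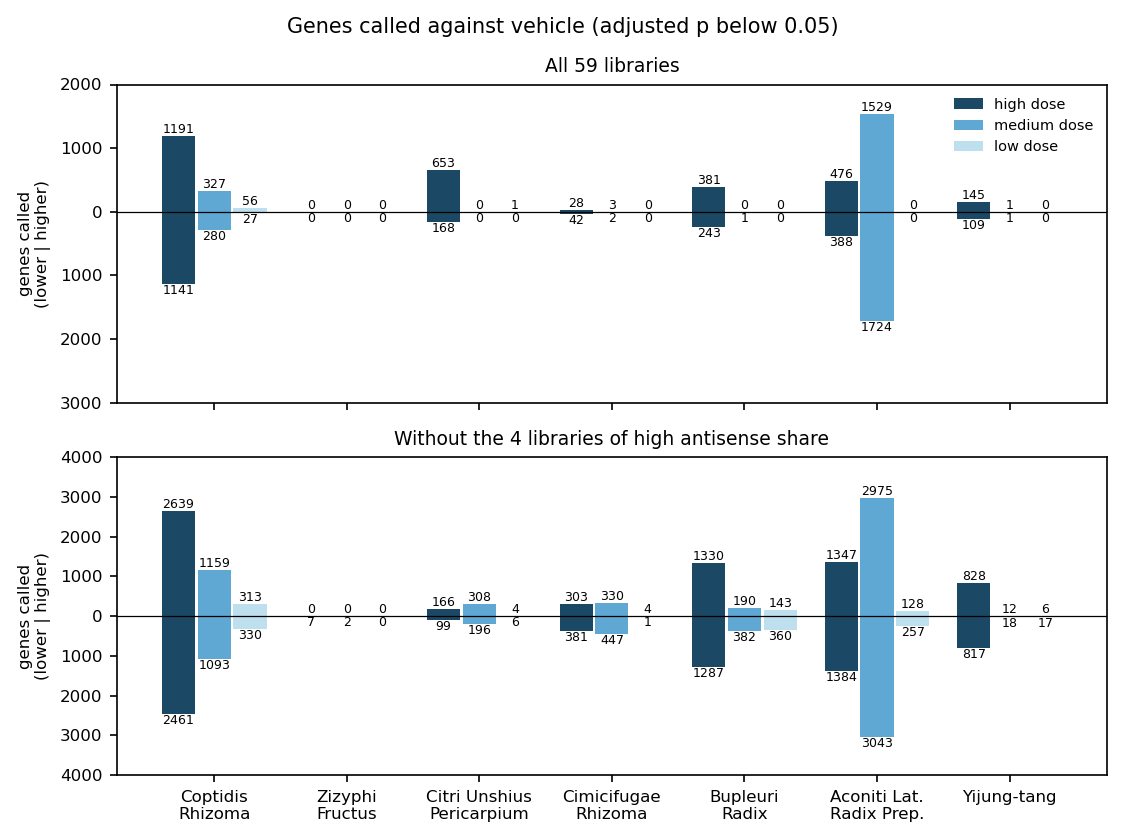
Number of genes called higher (above 0) and lower (below 0) than vehicle at each dose of 7 extracts, with all 59 libraries (upper panel) and without the 4 libraries of high antisense share (lower panel). Coptidis Rhizoma at the high dose had 1191 higher and 1141 lower genes, and Aconiti Lateralis Radix Preparata at the medium dose 1529 and 1724.

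Cimicifugae Rhizoma at the high dose raised AhR targets and HMOX1. CYP1A1 was at 6.06 ± 0.146 CPM (n = 3) against 0.749 ± 0.144 in vehicle (n = 3), 7.98-fold higher; CYP1B1 rose 2.77-fold, AHRR 2.36-fold and TIPARP, a further AhR-induced gene, 2.33-fold. HMOX1 (chromosome 22, ENSG00000100292, 35380361 to 35394214) was at 349 ± 9.46 against 168 ± 8.57 CPM, and RAP1GAP, which inactivates the small GTPase Rap1, at 49.4 ± 2.11 against 22.8 ± 2.21 CPM. NR4A1 (log2 change -1.49 ± 0.2), NR4A3 (-1.48 ± 0.23), the pyruvate dehydrogenase kinase gene PDK4 (-1.08 ± 0.15) and SUSD2 (-1 ± 0.12) fell. CYP1A1, CYP1B1, AHRR, RAP1GAP, HMOX1, NR4A1 and SUSD2 were called under every alternative run.

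Of the 6 AhR targets 4 rose (camera adjusted p = 3.24e-19, and 2.23e-08 with an estimated correlation), and 2 of 10 fatty acid synthesis genes did (9.67e-06; adjusted p = 0.0587 with an estimated correlation). Further lists passed both camera tests with 0 or 1 member called: DNA replication and metallothioneins downward, and cholesterol synthesis, LXR targets, and PXR and CAR targets upward (estimated-correlation adjusted p = 0.00789, 0.00367, 0.036, 0.0354 and 0.0354). In camera with the preset correlation 15 lists passed. Beside fatty acid synthesis, 8 were lost with an estimated correlation: heat shock proteins (adjusted p = 0.0587), NRF2 targets (0.109), G2/M genes (0.157), FOXO targets (0.183), TGF-beta genes (0.234), the respiratory chain (0.517), ATF4 targets (0.65) and mitochondrially encoded genes (0.653). With adjustment over the list alone, 4 AhR targets and 4 fatty acid genes were higher. edgeR called 70 genes, 28 higher and 42 lower, and 684 without the 4 libraries of high antisense share. The count was 34, 41 and 34 without high-dose replicate 1, 2 and 3, and 39 and 38 without vehicle replicate 1 and 2. A fit of only the Cimicifugae Rhizoma and vehicle libraries gave 12.

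At the medium dose of Cimicifugae Rhizoma CYP1B1 rose 1.66-fold to 91.8 ± 10.6 CPM and CYP1A1 3.92-fold to 2.97 ± 0.56 CPM, and RAP1GAP rose 1.54-fold. GINS1, a DNA replication gene, and DPH6 fell to 0.816 and 0.69 of vehicle, both calls lost in 7 of 12 alternatives. CYP1A1 and CYP1B1 each lost the call in 1 alternative, a fit of only the Cimicifugae Rhizoma and vehicle libraries, which called 0 genes, and RAP1GAP in 4 of 12. These were the 5 called genes, and 0 of them kept the call throughout; replicate 2, 1 of 3 at this dose, was a library of high antisense share. Without replicate 2 the count was 22, without replicate 1 it was 3, and without vehicle replicate 1, 2 and 3 it was 2, 2 and 3; without the 4 libraries it was 777. At the low dose edgeR called 0 genes, with 1263 at an unadjusted p below 0.05, 0 in DESeq2, 5 without the 4 libraries and 0 in a fit of only the Cimicifugae Rhizoma and vehicle libraries. Between the high and low dose 41 genes were called (13 higher, 28 lower), with CYP1A1 5.84-fold, CYP1B1 2.36-fold and HMOX1 1.99-fold higher and NR4A1 at 0.383. That count was 18 and 27 without high-dose replicate 1 and 2, 67 and 26 without low-dose replicate 1 and 2, 85 without the 4 libraries, and 2 in a fit of only the Cimicifugae Rhizoma libraries, where CYP1B1 and HMOX1 lost their calls.

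Citri Unshius Pericarpium at the high dose had libraries that differed widely among themselves, and its calls rested on a few libraries. CITED4, a transcriptional coregulator, was at 27.7 ± 17.7 CPM (n = 3) against 7.86 ± 0.719 in vehicle, and KRT19, an epithelial keratin, at 45.9 ± 32.5 against 22.4 ± 2.12 CPM. CYP1B1 was at 75.7 ± 7.49 against 55.3 ± 2.88 CPM, 1.37-fold higher, and CYP1A1 had 1.22 ± 0.696 CPM (adjusted p = 0.0878). TRIB3 had 101 ± 20.3 CPM and the MAPK phosphatase gene DUSP4 188 ± 49.1 against 140 ± 2.24 CPM. NR4A3 was at 5.16 ± 2.16 against 8.69 ± 0.869 CPM. Replicate 3, a library of high antisense share, was 1 of the 3 behind each of these means.

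By list, 2 of 6 AhR targets, 4 of 22 MAPK and immediate early genes, 1 of 20 ribosomal protein genes, 3 of 18 ribosome biogenesis genes and 3 of 12 lung epithelial markers were higher (camera adjusted p = 0.0408, 0.0408, 0.013, 0.013 and 0.0088). None of these 5 passed with an estimated correlation (adjusted p = 0.57, 0.86, 0.86, 0.86 and 0.66). The counts adjusted over the list alone were 3, 7, 2, 9 and 5. edgeR called 821 genes, 653 higher and 168 lower. The count was 4741, 3027 and 28 without high-dose replicate 1, 2 and 3, and 5, 0 and 7 without vehicle replicate 1, 2 and 3. It was 265 without the 4 libraries of high antisense share, 1760 in DESeq2 and 0 in a fit of only the Citri Unshius Pericarpium and vehicle libraries, and of the 25 called genes named by the rule 0 stayed called under every alternative.

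At the medium dose of Citri Unshius Pericarpium edgeR called 0 genes, with 2565 at an unadjusted p below 0.05, 14 in DESeq2 and 0 in a fit of only the Citri Unshius Pericarpium and vehicle libraries; CYP1B1 had 64.2 ± 11.6 CPM and TRIB3 102 ± 46.7 CPM. Without medium-dose replicate 1 that count was 1804, without replicate 3 it was 1, and without the 4 libraries of high antisense share 504. At the low dose it called 1 gene, the pseudogene RPSAP12, at 8.4 ± 1.09 against 2.89 ± 0.462 CPM. That count was 2 without low-dose replicate 2, 0 without any other 1 of the low-dose or vehicle libraries, 10 without the 4 libraries and 0 in a fit of only its own and the vehicle libraries. Its high and low dose differed in 657 genes, 579 higher and 78 lower at the high dose, led by SULT1A3 (14.3 ± 17.7 against 2.19 ± 0.559 CPM) and with the nuclear noncoding RNA MALAT1 at 617 ± 134 against 989 ± 242 CPM. That count was 4397, 2562 and 11 without high-dose replicate 1, 2 and 3, 0, 4 and 5 without low-dose replicate 1, 2 and 3, 156 without the 4 libraries, and 0 in a fit of only the Citri Unshius Pericarpium libraries. Replicates of the 2 doses that shared a number resembled each other (r across genes from 0.135 to 0.583), and with the replicate number as a block the count was 1387.

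Bupleuri Radix at the high dose raised lysosomal genes, cholesterol genes and AhR targets. UAP1L1, the largest rise, was at 25.8 ± 1.95 CPM (n = 3) against 5.35 ± 0.41 in vehicle (chromosome 9, ENSG00000197355, 137077501 to 137084539). RRAGD, a Rag GTPase that recruits mTORC1 to lysosomes, rose 3.63-fold, the lysosomal sialidase NEU1 2.71-fold to 39 ± 0.209 CPM, the lysosomal membrane protein CD68 3.62-fold and FLCN, folliculin, 2.06-fold. CYP1B1 was at 121 ± 1.1 against 55.3 ± 2.88 CPM, CYP1A1 at 2.94 ± 0.685 against 0.749 ± 0.144 CPM, and the immediate early gene EGR1 at 5.15 ± 1.58 against 1.14 ± 0.239 CPM. NR4A3 (log2 change -1.23 ± 0.23), the keratin KRT4 (-1.18 ± 0.23), TM4SF4 (-1.17 ± 0.1), the sulfotransferase SULT2B1 (-1.16 ± 0.18) and MYLIP, a ubiquitin ligase gene and LXR target (-1.08 ± 0.12), fell.

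Of 21 lysosome and autophagy genes 9 rose (camera adjusted p = 5.91e-15, and 4.08e-06 with an estimated correlation). Of 24 cholesterol genes 9 rose (7.34e-10 and 3.98e-05), with SQLE, LSS and FDFT1 higher by 0.44 ± 0.07, 0.47 ± 0.08 and 0.39 ± 0.06 on the log2 scale, while HMGCS1 (200 ± 9.32 against 201 ± 4.22 CPM) did not pass. AhR targets rose in 4 of 6 (estimated-correlation adjusted p = 1.94e-05), and LXR targets (1 of 7), DNA replication (4 of 29) and heat shock proteins (3 of 15) went down (0.005, 0.000156 and 0.04). FOXO targets had 5 of 11 members higher, including the atrophy gene FBXO32 and PDK4, with an adjusted p = 0.0521 with an estimated correlation. Of the 15 lists passing with the preset correlation 9 were lost with an estimated one: FOXO targets, G2/M genes and PXR and CAR targets (adjusted p = 0.0555 each for the last 2), NF-kB genes (0.223), TGF-beta genes (0.253), fatty acid synthesis (0.312), MAPK genes (0.403), mitochondrially encoded genes (0.47) and the respiratory chain (0.486). Adjusted over the list alone, 14 lysosome genes were higher and 1 lower, 11 cholesterol genes higher, 5 AhR targets higher and 6 FOXO targets higher. edgeR called 624 genes, 381 higher and 243 lower, 2617 without the 4 libraries of high antisense share and 4165 in a fit of only the Bupleuri Radix and vehicle libraries. The count was 311 and 291 without high-dose replicate 1 and 2, and 351, 313 and 342 without vehicle replicate 1, 2 and 3.

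At the medium dose of Bupleuri Radix 1 gene was called, PAFAH1B2, at 96.5 ± 4.31 against 120 ± 1.25 CPM, and 0 without any 1 of the 6 libraries. At the low dose edgeR called 0, with 1367 at an unadjusted p below 0.05 and 18 in DESeq2; without the 4 libraries of high antisense share the counts were 572 and 503, and in a fit of only the Bupleuri Radix and vehicle libraries 1914 and 1906. CYP1B1 had 71.5 ± 0.192 CPM at the medium and 60.8 ± 1.39 CPM at the low dose. Against the low dose, the high dose had UAP1L1 3.97-fold, RRAGD 3.5-fold and CYP1A1 3.29-fold higher and KRT4, H19 and the fibrinogen gene FGB at 0.398, 0.429 and 0.449. In that comparison 9 of 21 lysosome genes and 8 of 24 cholesterol genes were higher and 3 of 7 LXR targets lower, and each list passed with an estimated correlation (adjusted p = 9.99e-09, 3.28e-08 and 2.68e-05). There were 294 called genes, 190 higher and 104 lower, 1007 without the 4 libraries and 1532 in a fit of only the Bupleuri Radix libraries. The count was 178 and 160 without high-dose replicate 1 and 2, and 174, 180 and 167 without low-dose replicate 1, 2 and 3.

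Aconiti Lateralis Radix Preparata at the high dose raised inflammatory and immediate early genes and lowered FGB and FGA, 2 fibrinogen genes. CXCL8, a neutrophil-attracting chemokine and NF-kB target, was at 20.1 ± 3.16 CPM (n = 3) against 1.03 ± 0.311 in vehicle (chromosome 4, ENSG00000169429, 73740506 to 73743716), 19.9-fold higher, and EGR1 rose 13.2-fold to 15.3 ± 2.01 CPM. CDCP1, a transmembrane glycoprotein, rose 5.11-fold, the AP-1 subunit FOSB 4.99-fold and GREM1 4.43-fold. KRT4 was at 5.6 ± 0.493 against 28.4 ± 1.72 CPM, and FGB and FGA were at 0.335 and 0.385 of vehicle. FGFR3, a fibroblast growth factor receptor, fell by a log2 change of -1.39 ± 0.22.

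Of 18 NF-kB and inflammatory genes 9 rose (camera adjusted p = 6.56e-16, and 0.00153 with an estimated correlation), including CXCL2 (log2 change 1.29 ± 0.21) and TNFAIP3, a feedback inhibitor of NF-kB (0.88 ± 0.15). Of 22 MAPK and immediate early genes 10 rose (6.56e-16 and 0.0266), with DUSP4 at 0.81 ± 0.11. AhR targets rose in 5 of 6 (estimated-correlation adjusted p = 9.18e-05), with the aldehyde dehydrogenase ALDH3A1 at 1350 ± 19.8 against 683 ± 57.5 CPM and CYP1A1 at 2.24 ± 0.169 CPM. Of 22 p53 targets 5 rose (0.00349), and heat shock proteins (7 of 15), G2/M genes (3 of 25), DNA replication (4 of 29) and ER chaperones (1 of 19) went down (0.0012, 0.0385, 0.000274 and 0.0385). ATF4 targets, with 6 of 25 higher, had an adjusted p = 0.194 with an estimated correlation, and NRF2 targets, with 1 higher and 4 lower of 21, an adjusted p = 0.158. FOXO targets and the respiratory chain were also lost (adjusted p = 0.0984 and 0.511), so 8 of 12 lists passed both ways. Adjusted over the list alone, 15 NF-kB genes, 17 MAPK genes, 5 AhR targets, 6 p53 targets and 10 ATF4 targets were higher. edgeR called 864 genes, 476 higher and 388 lower, 2731 without the 4 libraries of high antisense share and 3805 in a fit of only the Aconiti Lateralis Radix Preparata and vehicle libraries. The count was 562 and 473 without high-dose replicate 1 and 2, and 516, 524 and 539 without vehicle replicate 1, 2 and 3.

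At the medium dose of Aconiti Lateralis Radix Preparata (n = 2) most of these folds were larger than at the high dose. FOSB was at 45.4 ± 3.13 CPM against 1.23 ± 0.175 in vehicle, EGR1 at 37.3 ± 0.174 against 1.14 ± 0.239, CXCL8 at 26 ± 2.63 against 1.03 ± 0.311, and KRT4 at 2.06 ± 0.161 against 28.4 ± 1.72 CPM. TRIB3 was at 256 ± 4.7 and ASNS at 310 ± 8.38 CPM, and HMGCS1 fell to 128 ± 1.99 CPM. CYP1A1 had 0.848 ± 0.126 CPM (adjusted p = 0.816) and CYP1B1 52.3 ± 1.18 CPM (adjusted p = 0.712). Of the lists, 21 of 22 MAPK and immediate early genes, 13 of 18 NF-kB genes and 20 of 25 ATF4 targets rose, and 16 of 24 cholesterol genes and 15 of 25 G2/M genes fell, each passing with an estimated correlation (adjusted p = 0.00578, 0.00413, 0.00933, 3.32e-06 and 0.00542). Adjusted over the list alone the counts were 21, 14, 20, 16 and 16. edgeR called 3253 genes, 1529 higher and 1724 lower, 6018 without the 4 libraries of high antisense share and 7048 in a fit of only the Aconiti Lateralis Radix Preparata and vehicle libraries; it was 2028 and 1855 without medium-dose replicate 1 and 2.

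A direct comparison of the medium with the high dose, added after the data had been seen, called 1445 genes, 583 higher and 862 lower at the medium dose, and 3678 without the 4 libraries of high antisense share. FOSB was higher by 2.87 ± 0.5 and EGR1 by 1.28 ± 0.38 on the log2 scale, and KRT4 lower at -1.44 ± 0.31. CYP1A1 and CYP1B1 were lower at -1.39 and -0.77 (adjusted p = 0.0016 and 7.19e-06). CXCL8 (0.37 ± 0.44, adjusted p = 0.764) and GREM1 (0.64 ± 0.29, adjusted p = 0.206) were not called in this comparison. At the low dose edgeR called 0 genes against vehicle, with 1214 at an unadjusted p below 0.05, 26 in DESeq2, 385 without the 4 libraries of high antisense share and 1164 in a fit of only the Aconiti Lateralis Radix Preparata and vehicle libraries. Between the high and low dose 610 genes were called, 290 higher and 320 lower, with CXCL8 24.2-fold and EGR1 11.4-fold higher and KRT4 at 0.175; 1774 were called without the 4 libraries and 2059 in a fit of only the Aconiti Lateralis Radix Preparata libraries. That count was 386 without high-dose replicate 1 and 358 without low-dose replicate 2. In this comparison 9 of 18 NF-kB genes and 12 of 22 MAPK genes were higher (estimated-correlation adjusted p = 0.000954 and 0.00923).

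Yijung-tang at the high dose raised genes of sterol and fatty acid synthesis. The sterol oxidase gene MSMO1 was at 106 ± 7.12 CPM (n = 2) against 41.2 ± 1.24 in vehicle (n = 3), and the squalene synthase gene FDFT1 at 263 ± 2.97 against 117 ± 5.4 CPM. SQLE rose 1.99-fold, LSS 2.18-fold and HMGCS1 1.69-fold. The desaturase genes FADS2 and FADS1 rose 2.11-fold and 1.97-fold. CYP1A1 was at 3.66 ± 0.426 against 0.749 ± 0.144 CPM, CYP1B1 at 133 ± 5.91 against 55.3 ± 2.88 CPM and TRIB3 at 148 ± 1.76 against 69.5 ± 3.21 CPM, while NR4A3 (log2 change -1.44 ± 0.26), NR4A1 (-1.26 ± 0.23) and NPTX1 (-1.05 ± 0.11) fell. NR4A3 lost its call without high-dose replicate 1.

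Of 24 cholesterol genes 18 rose and 0 fell (camera adjusted p = 2.78e-72, and 2.92e-15 with an estimated correlation), and of 10 fatty acid synthesis genes 6 rose (7.36e-19 and 0.000329). AhR targets rose in 4 of 6 and lysosome genes in 4 of 21, and heat shock proteins fell in 3 of 15, G2/M genes in 4 of 25 and DNA replication genes in 3 of 29 (estimated-correlation adjusted p = 1.8e-05, 0.0429, 0.00165, 0.000347 and 1.8e-05). ER chaperones passed upward with 0 of 19 called (0.000347). The 5 lists lost with an estimated correlation were ATF4 targets (2 of 25 higher, adjusted p = 0.18), NF-kB genes (1 of 18 higher, 0.18), TGF-beta genes (2 of 16 lower, 0.0783), FOXO targets (0.118) and the respiratory chain (0.537). With p adjusted over the list alone, 22 cholesterol genes, 7 fatty acid genes and 4 AhR targets were higher and 12 G2/M genes lower. edgeR called 254 genes, 145 higher and 109 lower, 1645 without the 4 libraries of high antisense share and 2961 in a fit of only the Yijung-tang and vehicle libraries. The count was 69 and 90 without high-dose replicate 1 and 2, and 151, 137 and 159 without vehicle replicate 1, 2 and 3.

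At the medium dose of Yijung-tang CYP1B1 rose 1.54-fold to 85.1 ± 5.49 CPM, and 2 genes were called in all; CYP1A1 had 1.92 ± 0.142 CPM (adjusted p = 0.354). The count was 0 without vehicle replicate 2 or 3 or either medium-dose replicate, 30 without the 4 libraries of high antisense share and 220 in a fit of only the Yijung-tang and vehicle libraries. At the low dose edgeR called 0 genes and DESeq2 5. Without the 4 libraries the edgeR count was 23, and in a fit of only the Yijung-tang and vehicle libraries 433. At an unadjusted p below 0.05 there were 743 at this dose, fewer than 0.05 of the tested genes. Against the low dose, the high dose had INSIG1 2.79-fold, MSMO1 2.73-fold and TRIB3 2.43-fold higher, and H19, the placental relaxin-like hormone gene INSL4 and FGB at 0.374, 0.435 and 0.455. In that comparison 18 of 24 cholesterol genes were higher (estimated-correlation adjusted p = 7.45e-19). There were 80 called genes, 53 higher and 27 lower, 416 without the 4 libraries and 642 in a fit of only the Yijung-tang libraries. The count was 41 and 51 without high-dose replicate 1 and 2, and 50 and 47 without low-dose replicate 1 and 2.

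**Figure D3:**
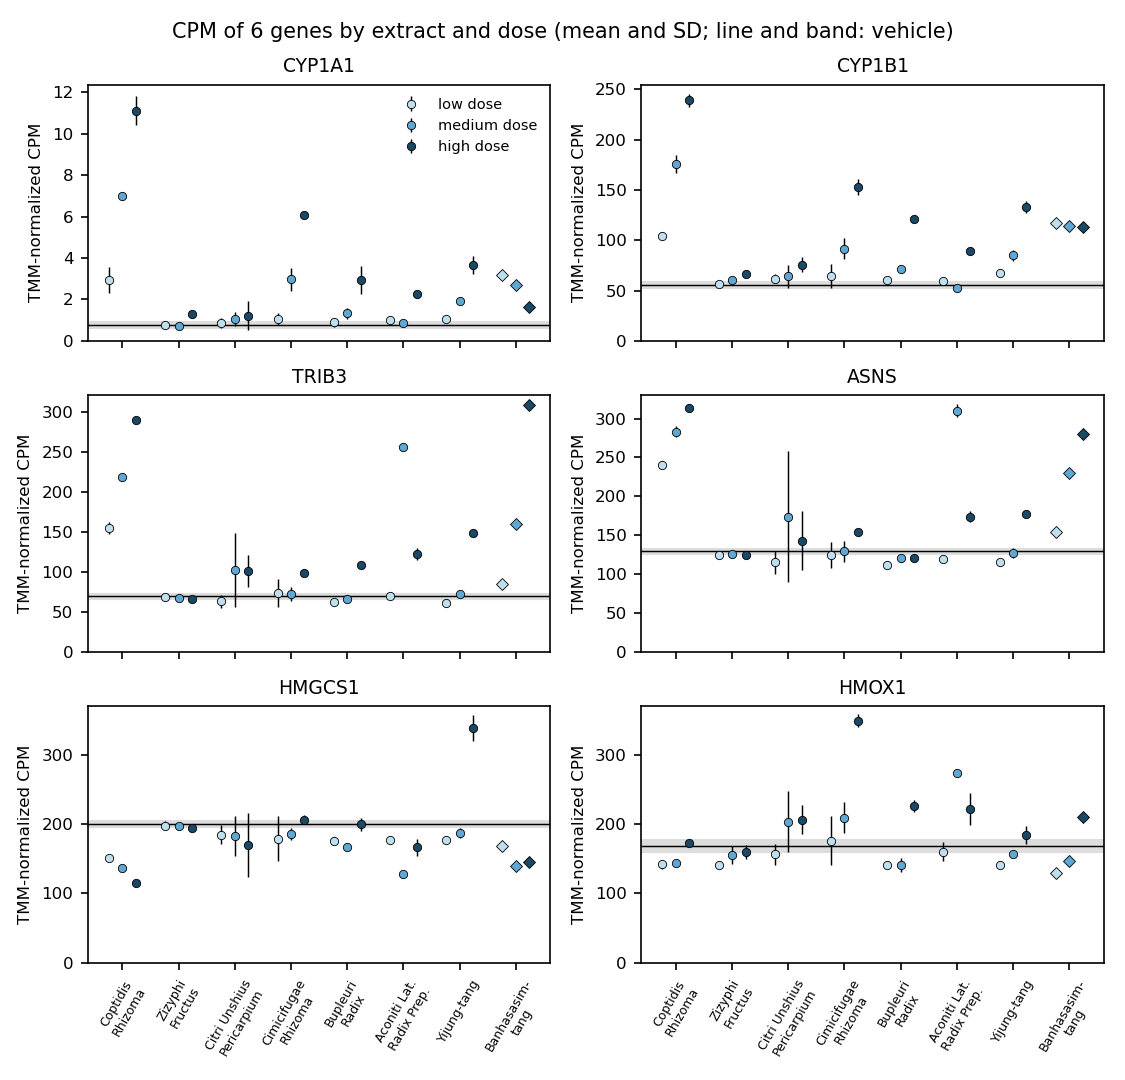
TMM-normalized CPM of 6 genes by extract and dose, as mean and SD, with the vehicle mean and SD as a line and band; diamonds are single libraries of Banhasasim-tang. CYP1A1 was at 11.1 CPM at the high dose of Coptidis Rhizoma and at 6.06 CPM at that of Cimicifugae Rhizoma, against 0.749 CPM in vehicle.

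In 3 pairs the extracts shared a library set and were compared directly at the high dose. Coptidis Rhizoma exceeded Zizyphi Fructus in MT-RNR1 (13.7-fold), BEX2 (10.1-fold), NIBAN1 (9.51-fold) and CYP1A1 (8.51-fold), and NR4A3, NR4A1, GPR37 and NPTX1 were at 0.221, 0.261, 0.294 and 0.3. AhR targets (5 of 6 higher), ATF4 targets (19 of 25 higher), cholesterol genes (17 of 24 lower) and G2/M genes (22 of 25 lower) each differed with an estimated correlation (adjusted p = 1.63e-06, 0.00107, 4.6e-09 and 1.63e-06). In total 1508 genes were called, 761 higher and 747 lower, 3733 without the 4 libraries of high antisense share and 5330 in a fit of only the libraries of these 2 extracts; the count was 732 and 806 without Coptidis Rhizoma replicate 2 and 3, and 793 and 778 without Zizyphi Fructus replicate 2 and 3.

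Citri Unshius Pericarpium was below Cimicifugae Rhizoma in AhR targets and HMOX1: CYP1A1 at 1.22 ± 0.696 against 6.06 ± 0.146 CPM, CYP1B1 at 75.7 ± 7.49 against 153 ± 8.24, AHRR at 3.03 ± 0.25 against 5.96 ± 0.191 and HMOX1 at 206 ± 21.1 against 349 ± 9.46 (n = 3 each). NR4A1 was 3.35-fold higher. AhR targets were lower in 4 and higher in 1 of 6 (estimated-correlation adjusted p = 0.00421). AHRR, HMOX1 and NR4A1 lost their calls in a fit of only the libraries of these 2 extracts, which called 6 genes. With all libraries 1425 genes were called, 1163 higher and 262 lower, and 451 without the 4 libraries of high antisense share. The count was 100, 125 and 111 without Cimicifugae Rhizoma replicate 1, 2 and 3, and 5051, 3036 and 108 without Citri Unshius Pericarpium replicate 1, 2 and 3. It was 2187 with the replicate number as a block.

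Bupleuri Radix exceeded Aconiti Lateralis Radix Preparata in UAP1L1 (3.14-fold), the steroid dehydrogenase gene HSD17B14 (2.64-fold), RAP1GAP (2.56-fold) and NEU1 (2.33-fold), and was below it in CXCL8 (2.05 ± 0.626 against 20.1 ± 3.16 CPM), the cholesterol exporter ABCA1 (5.38 ± 0.18 against 17.1 ± 1.09 CPM) and ESAM, an endothelial adhesion molecule (4.06 ± 1.01 against 11.4 ± 0.188 CPM). Lysosome genes (10 of 21 higher), cholesterol genes (4 of 24 higher), LXR targets (4 of 7 lower) and NF-kB genes (3 of 18 lower) differed with an estimated correlation (adjusted p = 1.08e-08, 3.54e-07, 1.87e-05 and 0.0061). In total 247 genes were called, 159 higher and 88 lower, 949 without the 4 libraries of high antisense share and 1516 in a fit of only the libraries of these 2 extracts. The count was 142, 150 and 157 without Aconiti Lateralis Radix Preparata replicate 1, 2 and 3, and 143 and 138 without Bupleuri Radix replicate 1 and 3.

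**Figure D4:**
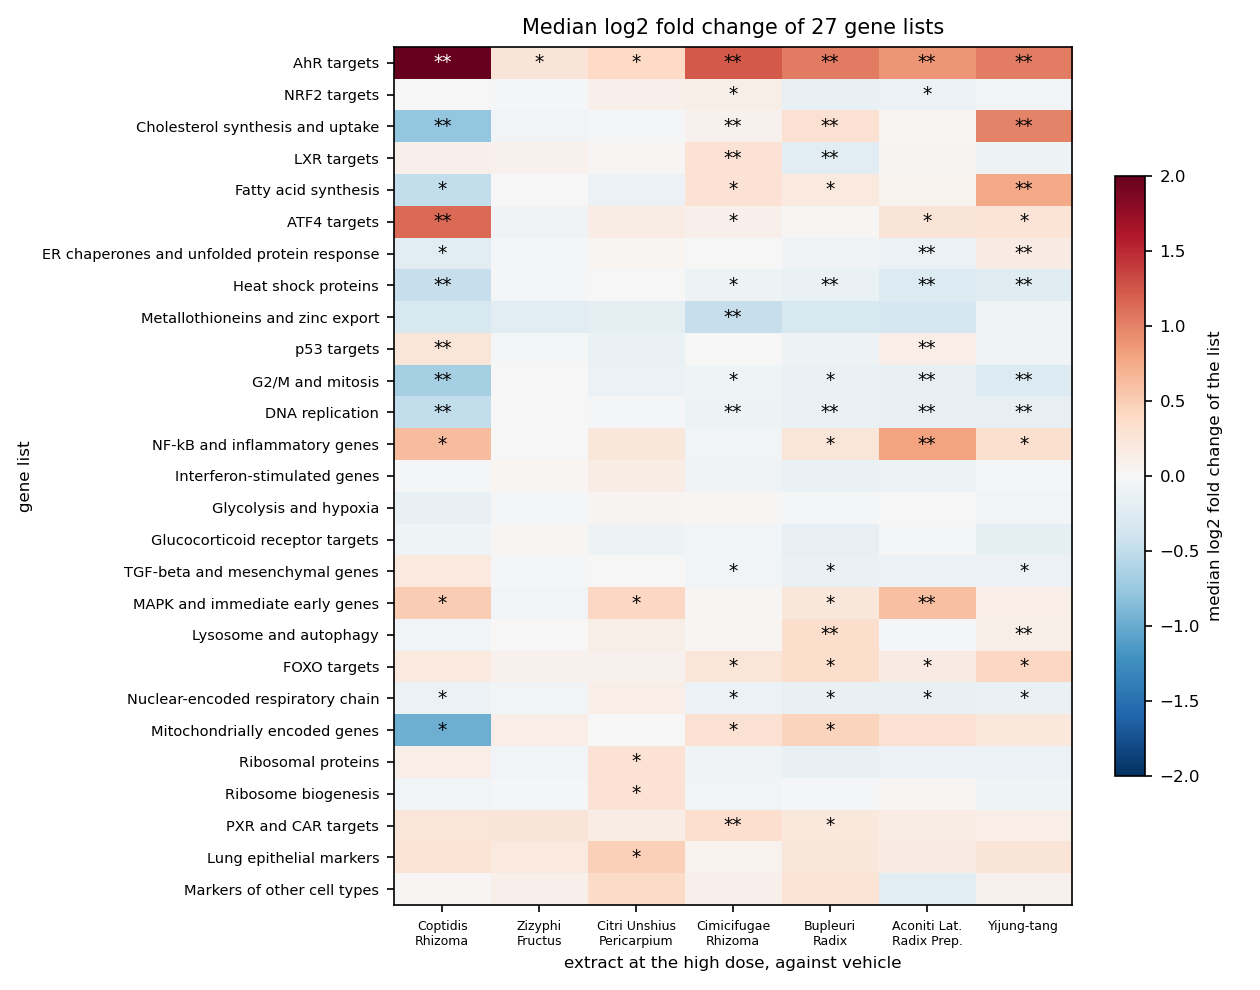
Median log2 fold change of 27 gene lists at the high dose of 7 extracts against vehicle. Stars mark a camera adjusted p below 0.05 with the preset correlation (1 star) and also with an estimated correlation (2 stars); cholesterol genes had a median of -0.776 with Coptidis Rhizoma and of 0.986 with Yijung-tang.

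Interferon-stimulated genes, glycolysis and hypoxia genes, glucocorticoid receptor targets and markers of other cell types passed no camera test at the high dose of any of 7 extracts. In this order, Coptidis Rhizoma had 1 higher and 1 lower of 14, 4 higher and 6 lower of 27, 1 higher and 2 lower of 10, and 0 higher and 2 lower of 9. Aconiti Lateralis Radix Preparata had 0 higher and 1 lower, 3 higher and 7 lower, 1 higher and 2 lower, and 1 higher and 1 lower of the same lists. With Aconiti Lateralis Radix Preparata the glycolytic genes ENO2 and HK2 rose and the carbonic anhydrase CA9 fell (log2 change 0.49 ± 0.08, 0.93 ± 0.18 and -1.37 ± 0.27). Other lists passed with some extracts, as given above. Of these, ribosomal proteins had 0 of 20 and ribosome biogenesis 0 of 18 members called with Coptidis Rhizoma. Metallothioneins had 1 of 4 lower with Coptidis Rhizoma and 0 of 4 with Cimicifugae Rhizoma, where the list median was -0.464. Lung epithelial markers had 3 higher and 2 lower of 12 with Coptidis Rhizoma. PXR and CAR targets had 1 of 4 higher with Bupleuri Radix, and TGF-beta and mesenchymal genes 2 higher and 3 lower of 16 with Coptidis Rhizoma.

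Banhasasim-tang, a formula that contains Coptis and jujube beside other medicines, had a single library per dose, so its folds have no error and were not tested. At the high dose MT-RNR1 was at 45500 CPM against 1560 ± 98.8 in vehicle (n = 3), NIBAN1 at 101 against 11.1 ± 0.802, BEX2 at 8.35 against 0.905 ± 0.139 and TRIB3 at 308 against 69.5 ± 3.21 CPM. HSPA1A had 92.5 against 344 ± 14.2 CPM, HSPA1B 59.8 against 207 ± 8.66, H19 26 against 84.8 ± 7.35 and PCDH17 1.34 against 5.15 ± 0.418 CPM. CYP1A1 had 1.65, 2.7 and 3.16 CPM at the high, medium and low dose, and HMGCS1 145, 140 and 168 CPM. CXCR5 and RN7SL2, also among its 5 largest rises and falls, had vehicle SDs of 5.85 and 31.6 CPM around means of 3.38 and 41.3, and EIF3CL is a near copy of another gene.

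The correlation across genes of high minus low log2 folds, which uses no vehicle library, was computed for all 28 pairs of extracts. Banhasasim-tang and Coptidis Rhizoma had r = 0.309 (0.261 to 0.28 with a replicate left out), and 0.688 over 10027 expressed genes. Aconiti Lateralis Radix Preparata and Bupleuri Radix had 0.294 (0.249 to 0.294 with a replicate left out), and 0.579 over the expressed genes. Aconiti Lateralis Radix Preparata and Coptidis Rhizoma had 0.288 (0.248 to 0.279), and 0.554 over the expressed genes, so the order of these 3 pairs is not settled. Cimicifugae Rhizoma and Citri Unshius Pericarpium had -0.373 (-0.468 to 0.105 with a replicate left out), and -0.727 over the expressed genes. Libraries of high antisense share enter this pair with opposite sign. They are replicate 3 at the high dose of Citri Unshius Pericarpium (2254 CPM) and replicate 2 at the low dose of Cimicifugae Rhizoma (2140 CPM). No correlation was computed without both, so opposite dose effects of these extracts cannot be read from this r. Banhasasim-tang and Zizyphi Fructus had 0.0271. Against vehicle the pair of Banhasasim-tang and Coptidis Rhizoma had r = 0.667. Simulated unchanged groups that shared simulated vehicle libraries had 0.314 on average, and the covariance of the pair exceeded theirs by 0.127. For Aconiti Lateralis Radix Preparata and Bupleuri Radix these values were 0.68, 0.497 and 0.0494. The simulation held no difference between the vehicle and the other libraries as a whole. Such a difference could also raise r, so these excesses alone do not show a response shared by 2 extracts. Genes are not independent replicates, and no p-value is attached to these correlations.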

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

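The strand test of the 4 libraries of high antisense share and, for Aconiti Lateralis Radix Preparata, the tests of a single library and of exchanged labels were written before their results were seen; the other tests of the 3 patterns below were chosen afterwards.

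Antisense noncoding genes took 1190 CPM in replicate 2 of Cimicifugae Rhizoma at the medium dose, 2140 in replicate 2 at its low dose, and 2254 and 1270 in replicate 3 of Citri Unshius Pericarpium at the high and medium dose, against at most 813.7 in vehicle; these genes enter no comparison as a class. The tables argue against an effect of the extract and dose, because the other replicates of these 4 groups had at most 768 CPM. The 4 libraries also have consecutive library codes that run across both extracts, but the labels do not say what the code order stands for. A partial loss of strand specificity stays open: the excess followed the sense partner with a rho of 0.0262 to 0.118 over the 4 libraries, and up to 0.0767 in other libraries. A bias toward short, GC-rich transcripts stays open, because a fit on GC content and length left 22.7% and -2.19% of the median antisense deviation in the Cimicifugae Rhizoma libraries at the medium and low dose and -148% in the Citri Unshius Pericarpium library at the high dose, but 64.1% in that at the medium dose. Over protein-coding genes that fit accounted for 30.7% to 46.8% of the variance of the deviations in the 4 libraries. In the other libraries with a replicate it accounted for a median of 11% and at most 29.5%. The 4 libraries thus also deviated by GC content and length outside the antisense genes. Genomic DNA stays open, with ratios from -0.113 to 0.112 between the gain in isolated and in antisense genes.

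Mitochondrial rRNA took 6.42% and 6.09% of counts in the high-dose libraries of Coptidis Rhizoma, 11.2% and 10.3% at the medium and 9.36% and 9.13% at the low dose, and 15.2%, 11.5% and 3.87% in the Banhasasim-tang libraries at the high, medium and low dose, against at most 2.43% in vehicle. In Coptidis Rhizoma more mitochondrial RNA of every kind is argued against by the 13 mitochondrial mRNAs, whose highest median log2 change over the 3 doses was -0.31, although MT-ND5, MT-ND6 and MT-CYB rose by 2.56, 2.71 and 1.92 at the low dose. At the high dose of Coptidis Rhizoma MT-RNR1 rose by 3.75 and MT-RNR2 by 0.84. In Banhasasim-tang the median was -0.13 and 0.22 in the high-dose and medium-dose libraries, with 5 and 8 of 13 mRNAs higher. The upper quartiles of 0.54 and 1.4 lay under the bounds of 1.84 and 1.65 drawn from the mean change of MT-RNR1 and MT-RNR2. The medium-dose bound leaned on MT-RNR1 (4.51, against 2.11 for MT-RNR2). In that library MT-ND5, MT-ND6 and MT-CYB rose by 3.1, 3.21 and 2.05. These values argue against a rise of all 13 mRNAs in the high-dose and medium-dose libraries, but not against a rise of some. In the low-dose library more mitochondrial RNA of every kind stays open. There the median was 0.49, with 12 of 13 higher and an upper quartile of 0.93 above the bound of 0.68. Carry-over of RNA without a long poly(A) tail is argued against by histone and small stable RNAs in 3 cases. Their median log2 change was 0.03 at the low dose of Coptidis Rhizoma, the only dose the test used (-0.09 at its high and medium dose). It was 0.05 and -0.06 at the medium and low dose of Banhasasim-tang. At the high dose of Banhasasim-tang (-0.07) the test cannot decide. Of the 38 genes 34 are histone genes expressed with DNA replication, and 29 of 29 DNA replication genes were lower there (median -0.53). In the 3 cases above the DNA replication genes were lower too, but by less. Their medians were -0.13 at the low dose of Coptidis Rhizoma, and -0.16 and -0.11 at the medium and low dose of Banhasasim-tang. This weakens the test in these cases as well. For Coptidis Rhizoma and the high-dose and medium-dose libraries of Banhasasim-tang, a difference between library sets is argued against by Zizyphi Fructus and Yijung-tang, from the same sets, with at most 3.12%. For the low-dose library of Banhasasim-tang it stays open: Yijung-tang reached 48.1% of its gap to the highest vehicle library, and libraries of other sets reached 3.25%. No biological explanation was tested.

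Between the medium and the high dose of Aconiti Lateralis Radix Preparata 1445 genes differed, with more genes called against vehicle at the medium dose (3253) than at the high dose (864). A single medium-dose library as the source is argued against by the SD of log2 folds, 0.393 in the lower of the 2 libraries and at most 0.243 in a high-dose library. A difference of the library set is argued against because both doses are in 1 set and still differed in these 1445 genes, and because Bupleuri Radix, in the same set, had fewer called genes at the medium than at the high dose in every setting (1 against 624 with all libraries, and 1914 against 4165 in a fit of its own and the vehicle libraries). A difference shared by the medium-dose libraries of the set is argued against too: over the 1445 genes the median change of Aconiti Lateralis Radix Preparata was 0.64 on the log2 scale, and the medium dose of Bupleuri Radix moved the same way by a median of -0.08, 0.03 and -0.04 against its high dose, its low dose and vehicle (upper quartiles 0.03, 0.09 and 0.07). Exchanged labels of the medium and high dose predict similar folds of different size, and r over genes called at either dose was 0.835; a response that falls off at the high dose predicts the same r, so the test does not separate them. CYP1A1 and CYP1B1 went the other way, lower at the medium dose by a log2 change of -1.39 and -0.77.

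The 6 libraries of each comparison of 3 against 3 make 10 splits into equal groups, which cannot give a share under 0.05. In comparisons with vehicle the real split also parts a library set from the vehicle, so its count cannot separate an extract from its set. Fitted on those 6 libraries alone, the real split called 849 genes for Cimicifugae Rhizoma at the high dose (highest other split 2), 4301 and 4142 for Bupleuri Radix and Aconiti Lateralis Radix Preparata at the high dose (0 and 0), 1997 for Bupleuri Radix at the medium dose (1), 1284 and 791 for Bupleuri Radix and Aconiti Lateralis Radix Preparata at the low dose (2 and 2), 1 for Citri Unshius Pericarpium at the low dose (0), 1349 and 1954 for the high against the low dose of Bupleuri Radix and Aconiti Lateralis Radix Preparata (1 and 0), and 1561 between these 2 extracts (3); in each, 1 of 10 splits called as many. The real split called 0 for Citri Unshius Pericarpium at the high and medium dose (highest other 0 and 0), for Cimicifugae Rhizoma at the medium and low dose (1 and 0), for the high against the low dose of both (0 and 0) and between them (0). In each, 10 of 10 splits called as many, which a real count of 0 makes certain, so these splits decide nothing. The split fits ignored the replicate number, although replicates of Citri Unshius Pericarpium at the high and low dose that shared a number resembled each other.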

How the results depend on the processing

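The fit without the 4 libraries of high antisense share was chosen after the data had been seen; the other alternatives were chosen beforehand. Of 8334 pairs of a named gene and an alternative, 7526 kept both their direction and their side of the threshold. Another 445 lost a call, 237 gained one, 126 were uncalled genes that changed sign, and 0 called genes reversed. Only 3889 of the pairs were of genes called in the main fit, and the 445 lost calls are all among these. Of 379 alternative values of the counts, list tests and correlations, 168 stayed within 1.5 times the reported value, or its spread for the correlations, and 211 did not. With RLE size factors no count of called genes left that range. The cause was not tested unless given here. With DESeq2 the counts outside it were Zizyphi Fructus high 3, Citri Unshius Pericarpium high 1760, Cimicifugae Rhizoma high 118, Yijung-tang high 409, Zizyphi Fructus medium 2, Citri Unshius Pericarpium medium 14, Cimicifugae Rhizoma medium 32, Bupleuri Radix medium 21, Coptidis Rhizoma low 152, Citri Unshius Pericarpium low 3, Bupleuri Radix low 18, Aconiti Lateralis Radix Preparata low 26, Yijung-tang low 5, Citri Unshius Pericarpium high against low 1583, Cimicifugae Rhizoma high against low 62, Yijung-tang high against low 132. With no low-count filter, which raised the tested genes from 18568 to 36918, they were Zizyphi Fructus high 27, Citri Unshius Pericarpium high 2100, Cimicifugae Rhizoma high 110, Zizyphi Fructus medium 61, Citri Unshius Pericarpium medium 642, Cimicifugae Rhizoma medium 123, Bupleuri Radix medium 131, Yijung-tang medium 51, Coptidis Rhizoma low 130, Zizyphi Fructus low 40, Citri Unshius Pericarpium low 103, Cimicifugae Rhizoma low 273, Bupleuri Radix low 131, Aconiti Lateralis Radix Preparata low 79, Yijung-tang low 55, Coptidis Rhizoma high against low 285, Zizyphi Fructus high against low 14, Citri Unshius Pericarpium high against low 2063, Cimicifugae Rhizoma high against low 446, Yijung-tang high against low 123, Citri Unshius Pericarpium against Cimicifugae Rhizoma 2510. With only the libraries of the extracts compared, whose spread then comes from fewer libraries, they were Coptidis Rhizoma high 7089, Zizyphi Fructus high 2, Citri Unshius Pericarpium high 0, Cimicifugae Rhizoma high 12, Bupleuri Radix high 4165, Aconiti Lateralis Radix Preparata high 3805, Yijung-tang high 2961, Coptidis Rhizoma medium 4185, Zizyphi Fructus medium 19, Cimicifugae Rhizoma medium 0, Bupleuri Radix medium 1914, Aconiti Lateralis Radix Preparata medium 7048, Yijung-tang medium 220, Coptidis Rhizoma low 2126, Citri Unshius Pericarpium low 0, Bupleuri Radix low 1906, Aconiti Lateralis Radix Preparata low 1164, Yijung-tang low 433, Coptidis Rhizoma high against low 4206, Citri Unshius Pericarpium high against low 0, Cimicifugae Rhizoma high against low 2, Bupleuri Radix high against low 1532, Aconiti Lateralis Radix Preparata high against low 2059, Yijung-tang high against low 642, Coptidis Rhizoma against Zizyphi Fructus 5330, Citri Unshius Pericarpium against Cimicifugae Rhizoma 6, Bupleuri Radix against Aconiti Lateralis Radix Preparata 1516. Without the 4 libraries of high antisense share they were Coptidis Rhizoma high 5100, Zizyphi Fructus high 7, Citri Unshius Pericarpium high 265, Cimicifugae Rhizoma high 684, Bupleuri Radix high 2617, Aconiti Lateralis Radix Preparata high 2731, Yijung-tang high 1645, Coptidis Rhizoma medium 2252, Zizyphi Fructus medium 2, Citri Unshius Pericarpium medium 504, Cimicifugae Rhizoma medium 777, Bupleuri Radix medium 572, Aconiti Lateralis Radix Preparata medium 6018, Yijung-tang medium 30, Coptidis Rhizoma low 643, Citri Unshius Pericarpium low 10, Cimicifugae Rhizoma low 5, Bupleuri Radix low 503, Aconiti Lateralis Radix Preparata low 385, Yijung-tang low 23, Coptidis Rhizoma high against low 1643, Citri Unshius Pericarpium high against low 156, Cimicifugae Rhizoma high against low 85, Bupleuri Radix high against low 1007, Aconiti Lateralis Radix Preparata high against low 1774, Yijung-tang high against low 416, Coptidis Rhizoma against Zizyphi Fructus 3733, Citri Unshius Pericarpium against Cimicifugae Rhizoma 451, Bupleuri Radix against Aconiti Lateralis Radix Preparata 949. With the replicate number as a block they were Citri Unshius Pericarpium high against low 1387, Citri Unshius Pericarpium against Cimicifugae Rhizoma 2187, and 5 lists passed for Zizyphi Fructus at the high dose. With an estimated correlation the numbers of lists passing camera were Coptidis Rhizoma high 7, Zizyphi Fructus high 0, Citri Unshius Pericarpium high 0, Cimicifugae Rhizoma high 6, Bupleuri Radix high 6, Yijung-tang high 8. With each replicate left out in turn, where a lone library is assumed to vary like the other groups, counts ran as follows: Coptidis Rhizoma high 1164 to 1773, Citri Unshius Pericarpium high 0 to 4741, Cimicifugae Rhizoma high 34 to 47, Bupleuri Radix high 291 to 465, Aconiti Lateralis Radix Preparata high 473 to 589, Yijung-tang high 69 to 159, Coptidis Rhizoma medium 228 to 415, Citri Unshius Pericarpium medium 0 to 1804, Cimicifugae Rhizoma medium 2 to 22, Bupleuri Radix medium 0 to 0, Aconiti Lateralis Radix Preparata medium 1855 to 2667, Yijung-tang medium 0 to 2, Coptidis Rhizoma low 28 to 54, Citri Unshius Pericarpium low 0 to 2, Coptidis Rhizoma high against low 110 to 150, Citri Unshius Pericarpium high against low 0 to 4397, Cimicifugae Rhizoma high against low 18 to 67, Bupleuri Radix high against low 160 to 211, Aconiti Lateralis Radix Preparata high against low 358 to 418, Yijung-tang high against low 41 to 51, Coptidis Rhizoma against Zizyphi Fructus 732 to 806, Citri Unshius Pericarpium against Cimicifugae Rhizoma 100 to 5051, Bupleuri Radix against Aconiti Lateralis Radix Preparata 138 to 169. The correlation of Banhasasim-tang with Coptidis Rhizoma was 0.667 with folds over vehicle, 0.688 in expressed genes and 0.261 to 0.28 with a replicate left out, and that with Zizyphi Fructus was 0.321, 0.0446 and 0.00939 to 0.0351. What depth limits was not tested; at 1.5-fold the test on simulated data recovered 45% of changed genes with 2 against 3 libraries.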

Other observations

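The values below were chosen after they were seen, and no explanation was tested for them. Within the ER chaperone list, Coptidis Rhizoma at the high dose raised HSPA5, HERPUD1, XBP1 and HYOU1 and lowered PDIA3, PDIA4, PDIA6, DNAJB11, SDF2L1, MANF and CALR, so 4 members rose and 7 fell. In the lung epithelial list LAMP3 rose by 4.29 on the log2 scale, and among interferon-stimulated genes MX1 rose by 1.49 while OAS1 was at -0.85. Heat shock proteins as a list were below vehicle also at the low dose of Coptidis Rhizoma (camera adjusted p = 0.000276 with an estimated correlation) with 0 of 15 members called, and 7 when adjusted over the list alone.

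Markers of other cell types had 1 higher (CD68) and 4 lower (COL1A1, COL3A1, THY1 and CD14) of 9 members at the medium dose of Aconiti Lateralis Radix Preparata, with a camera adjusted p = 0.0204, and 0.0594 with an estimated correlation.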
